A study of Mus musculus with 44 samples.

How the data were processed

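The labels describe 44 blood samples of FVB mice in 6 groups, and 1 library of the paclitaxel and PMX-53 combination group, replicate 8, was analysed here. The other 43 samples were not analysed here. Per the labels' protocols, DNA was isolated from lysates of peripheral blood mononuclear cells (PBMCs), and the libraries were made by PCR for an Illumina NextSeq sequencer. The target was the third complementarity-determining region (CDR3) of the T cell receptor beta chain, the joint of the V, D and J segments that differs from 1 T cell clone to the next. Genomic DNA carries 1 template per rearranged allele, so a cell's RNA level does not enter the counts. Copies made by PCR do, since no molecular identifiers are recorded.

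The deposited table has a row per clonotype, that is, per distinct CDR3 nucleotide sequence. Per the file headers, each row holds V, D and J hits, the CDR3 in bases and amino acids, the clone count, the clone fraction, a normalized clone count and a normalized clone fraction. The raw clone count deposited by the authors is a whole number of reads per clonotype. The fraction columns deposited by the authors equal each count divided by its column sum. The normalized clone count is a score, treated as a normalized value that the authors rounded to whole numbers and not as reads. Its ratio to the raw count was nearly constant within a V-J pair: over the 77 pairs with at least 2 clonotypes of 20 or more reads, the highest ratio of a pair exceeded its lowest by at most a factor of 1.125. The origin of these factors, the alignment program, its version and the germline reference are not given in the sources used here. The lowest base quality score of the CDR3, a column named in the file headers, ran from 21 to 40. The table held CDR3s in frame and without a stop codon for all 4646 clonotypes, so the planned comparison with nonproductive rearrangements could not be made. Clone IDs ran to 6805 and followed falling clone count without exception; 2160 IDs up to that value, among them 20 of the first 100, are not used here. The first listed ID was 2. Ranks by size, shares of reads and clonality therefore cover the listed clonotypes alone.

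Each clonotype was given its best V and J hit. Segment names were matched to the mouse gene table of assembly GRCm38.p6 for symbols, gene type and order along the chromosome, and 36 of 36 segments matched. No coordinates are given, because no build is named for the files. V and J usage and CDR3 length were computed over distinct clonotypes, each counted once, and clonality and the share of the largest clonotypes were computed from the authors' normalized counts. Clonality was 1 minus the Shannon entropy divided by its maximum, over clonotypes with a normalized count above 0, with a standard error from multinomial sampling of the reads. Shares have exact Clopper-Pearson 95% intervals over the clonotypes or reads counted. For a segment with 0 clonotypes, the limit given is 3 counts of the total, a one-sided bound that lies below the upper end of the exact two-sided interval (0.0794%). For the normalized share of the 10 largest clonotypes, the interval takes the 45457 raw reads as the number of draws. It leaves out the V-J factors, which multiply the error of counts scaled up, so it is too narrow. The standard error of clonality leaves them out too. All intervals cover counting error only, and PCR copies are not independent molecules. With 1 library no test between groups was made, no p-value is given and no spread between animals can be stated; an SD given for CDR3 length is over clonotypes.

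The V and J lists, the main settings and the rule for the named segments and clonotypes were set before the data were examined. The V list held 10 segments of the block from TRBV12-1 to TRBV17, described as deleted in FVB and some other strains, and a comparison list held 13 V segments outside it. The rule named each member of the block, the 10 V segments with most clonotypes, each J segment, the 10 most used V-J pairs, the 20 largest clonotypes by normalized count, the 10 CDR3 amino acid sequences with most nucleotide sequences, and the 3 V and 3 J segments most raised and most lowered by the normalization. It also named V segments that differ between productive and nonproductive rearrangements, which had no members here. Alternatives were a minimum clone count of 2, joining clonotypes 1 base apart to a neighbour at least 10 times larger, raw counts in place of normalized counts, amino acid clonotypes, thinning to 50 percent of the reads, leaving out the largest clonotype, segments with a single hit, and expanded sets of 20 and 500. The functions were tested on simulated data: of 200 near-copies planted among 2000 simulated clonotypes of this library, 200 were joined. The simulated CDR3s were random bases, and each copy had 1 read beside a source more than 10 times larger. The rule for joining was thus met by construction. The check covers the code alone and not how often real clonotypes are wrongly joined or missed. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.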

Results

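The study sequenced the beta chain CDR3 of T cells in blood of FVB mice given paclitaxel, PMX-53, both or neither, with 8 untreated controls, 10 paclitaxel, 8 PMX-53 and 8 combination samples, and 5 samples in each of a pair of groups whose titles begin with NTB. Its title places the samples in a study of the complement fragment C5a in squamous carcinogenesis and of clonal T cell responses to chemotherapy. The labels give all samples an age of postnatal day 110 to 140. Paclitaxel is a microtubule-stabilising chemotherapy, given into a vein at 12 mg/kg every 4 days with 3 injections per cycle. PMX-53 is a cyclic peptide antagonist of a C5a receptor, delivered by implanted pump at 1.0 mg/kg per day from day 40, when carcinomas had reached about 50 mm3. The library described here is combination replicate 8, so the comparisons between treatments were not made, and the values below describe the clonotypes listed for that 1 library. The 4646 listed clonotypes held 45457 reads, with 54430 normalized counts. Read numbers listed with them ran up to 223753, so the listed reads may be only a part of those sequenced.

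No listed clonotype was above 1 percent of the listed reads. Clone IDs follow falling clone count, and 2 IDs before that of the largest listed clonotype, and 20 of the first 100, are not used here, so the shares and clonality below describe the listed clonotypes and not the whole library. The largest was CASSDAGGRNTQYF, a TRBV13-3 and TRBJ2-5 rearrangement with 232 reads, 0.510% of the reads (95% interval 0.447 to 0.580) and 0.310% of the normalized counts. The next by reads was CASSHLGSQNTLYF, a TRBV12-1 and TRBJ2-4 rearrangement with 168 reads, or 0.370% (0.316 to 0.430). These intervals do not overlap, so both clonotypes differed in size by more than counting error. The third, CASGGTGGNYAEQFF of TRBV13-2 and TRBJ2-1, had 80 reads, or 0.176% (0.140 to 0.219). Only 13 listed clonotypes exceeded 50 reads. The 10 largest clonotypes by normalized count held 2.40% of the normalized counts (2.26 to 2.54). The 10 largest by reads, a different set, held 2.05% of the raw reads (1.92 to 2.19). The first of these intervals leaves out the scaling by V-J factors and is too narrow. The 100 largest by normalized count held 12.9% of the normalized counts, and the 100 largest by reads held 9.62% of the reads. Only 19 clonotypes were in both sets of 100. Clonality, which is 0 for an even repertoire and 1 for a single clone, was 0.0541 ± 0.00048 (standard error of counting) over the 4467 clonotypes with a normalized count above 0.

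The median clonotype had 7 reads. Among the 2655 clonotypes with 5 or more reads the median was 14, with quartiles of 9 and 21. Clonotypes with a single read numbered 1313, or 28.3% of the total. Of these, 752 (57.3%) differed by 1 base from a larger clonotype of the same V, J and length.

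Over distinct clonotypes, V segment usage was led by TRBV24, with 940 clonotypes or 20.2% (95% interval 19.1 to 21.4), and TRBV1, with 731 or 15.7% (14.7 to 16.8). TRBV2 followed with 9.51% (8.68 to 10.4), TRBV3 with 8.03% (7.26 to 8.85) and TRBV5 with 7.49% (6.75 to 8.29). In this count the order of TRBV24, TRBV1 and TRBV2 stood outside counting error. The interval of TRBV3 overlapped those of both TRBV2 and TRBV5. Weighted by normalized count, the order after TRBV24 (19.0%) changed to TRBV4 (12.2%), TRBV5 (10.6%) and TRBV1 (10.5%). TRBV24, TRBV1 and TRBV2 together made up 45.5% of the clonotypes (44.0 to 46.9). TRBV13-2 had 6.09% (5.42 to 6.82), TRBV29 had 5.51% (4.87 to 6.21), TRBV19 had 4.99% (4.38 to 5.66), TRBV4 had 4.76% (4.16 to 5.41) and TRBV26 had 3.53% (3.02 to 4.10). Of the 13 V segments on the comparison list, 12 were seen. TRBV31, which lies in inverted orientation on the far side of the constant regions, had 0 of 4646 clonotypes, which by the rule of 3 counts allows a share of up to 0.0646%. That limit holds only if the PCR and the alignment could pick up the segment, which was not checked. TRBV10 and TRBV22, annotated as pseudogenes in the gene table, had 1 and 7 clonotypes. TRBV29, also annotated as a pseudogene in that table for the C57BL/6J strain, had 256.

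The block of V segments from TRBV12-1 to TRBV17, described as deleted in FVB mice, was represented by 9 of its 10 members. Together they made up 836 of 4646 clonotypes, or 18.0% (95% interval 16.9 to 19.1), against 81.8% (80.7 to 82.9) for the comparison list outside the block. The TRBV13 family alone held 544 clonotypes, or 11.7% (10.8 to 12.7). TRBV13-2 had 283 clonotypes, TRBV13-1 had 144 (3.10%, 2.62 to 3.64), TRBV13-3 had 117 (2.52%, 2.09 to 3.01) and TRBV12-1 had 103 (2.22%, 1.81 to 2.68). TRBV16 had 64 (1.38%), TRBV12-2 had 45 (0.969%), TRBV14 had 42 (0.904%), TRBV15 had 34 (0.732%) and TRBV17 had 4 (0.0861%). TRBV12-3, a pseudogene, had 0 clonotypes, with the same limit of 0.0646%. The block held 16.8% of the reads and 11.1% of the normalized counts.

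**Figure D1:**
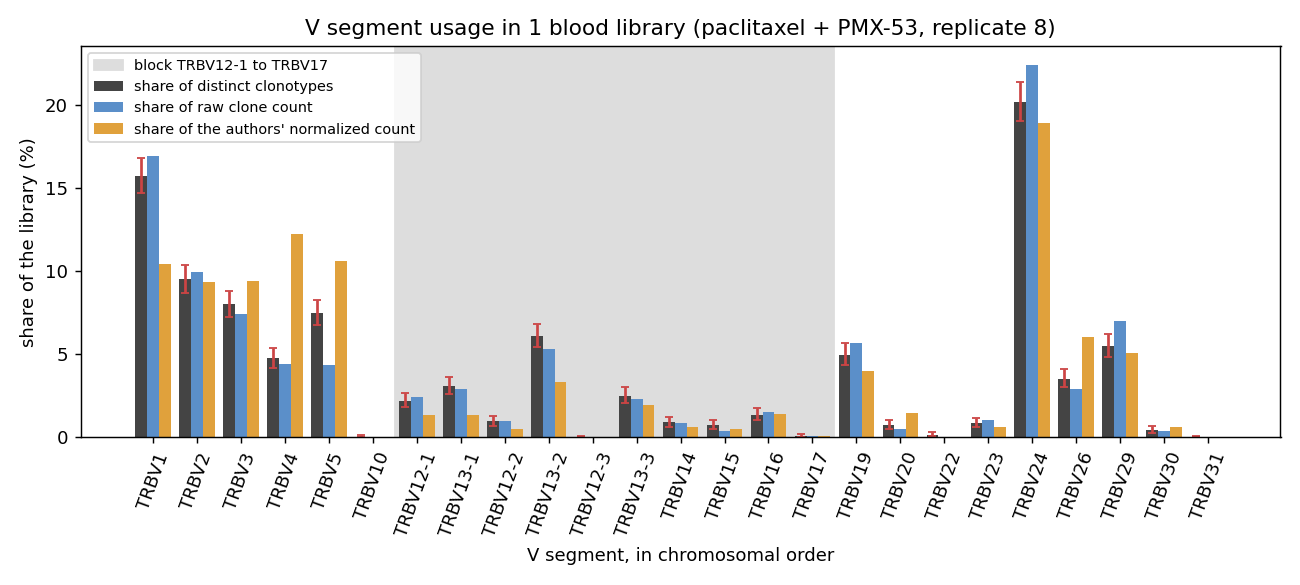
Share of the listed clonotypes, reads or normalized counts in percent (vertical axis) for each V segment in chromosomal order (horizontal axis). Bars give distinct clonotypes with exact 95% intervals as error bars, raw clone count and normalized count. TRBV24 led all measures; the shaded block held 18.0% of the clonotypes and 11.1% of the normalized counts, and TRBV4 went from 4.40% of the reads to 12.2% of the normalized counts.

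The TRBJ2 cluster was used in 75.6% of clonotypes (95% interval 74.3 to 76.8) and the TRBJ1 cluster in 24.4% (23.2 to 25.7). TRBJ2-7 was the most used J segment, with 934 clonotypes or 20.1% (19.0 to 21.3), then TRBJ2-5 with 696 clonotypes or 14.98% (13.97 to 16.04), TRBJ2-1 with 12.1% (11.15 to 13.05), TRBJ2-3 with 11.3% (10.4 to 12.3), TRBJ2-4 with 10.2% (9.33 to 11.1) and TRBJ2-2 with 6.89% (6.18 to 7.65). TRBJ2-6, a pseudogene, had 0 clonotypes. In the other cluster, TRBJ1-1 had 7.75% (7.00 to 8.56) and TRBJ1-2 had 6.26% (5.58 to 7.00). TRBJ1-4 had 3.27%, TRBJ1-6 had 3.21%, TRBJ1-3 had 1.98% and TRBJ1-5 had 1.92%. TRBJ1-7 had 2 clonotypes. Of the 299 possible pairs of the 23 V and 13 J segments seen, 233 occurred. The pair with most clonotypes was TRBV24 with TRBJ2-7 (TRBV24_TRBJ2-7), with 181 or 3.90% (3.36 to 4.49). It was followed by TRBV24 with TRBJ2-5 (145 clonotypes), TRBV5 with TRBJ2-7 (136), TRBV1 with TRBJ2-5 (121), TRBV24 with TRBJ2-3 (117), TRBV24 with TRBJ2-1 (113), TRBV24 with TRBJ2-4 (111), TRBV3 with TRBJ2-7 (109), and TRBV1 with TRBJ2-3 and TRBV2 with TRBJ2-5 (105 each).

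The median CDR3 was 14 amino acids long, and 88.5% of clonotypes (95% interval 87.6 to 89.4) had 12 to 16. The mean was 14.6 ± 4.05 (SD over 4646 clonotypes). A separate group of 159 clonotypes had 28 or more amino acids, and 158 of these were TRBV26 rearrangements, out of 164 with that segment. Their median was 35, and 156 of the 158 held the sequence LYLCA inside the deposited CDR3. Without them the mean was 13.9 ± 1.60 (SD over 4488 clonotypes). In all, 4393 CDR3s (94.6%) ran from a cysteine to a phenylalanine, the residues that bound a conventional CDR3.

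**Figure D2:**
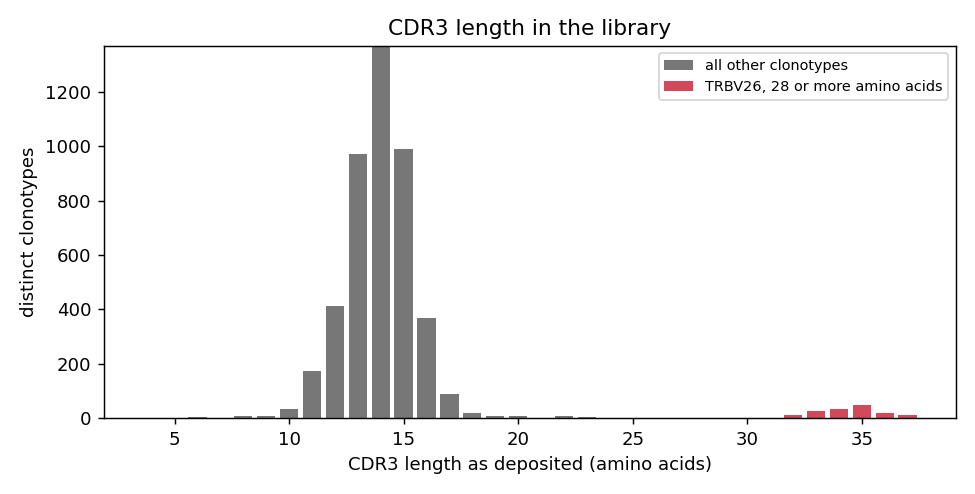
Number of distinct clonotypes (vertical axis) by CDR3 length in amino acids as deposited (horizontal axis), with TRBV26 clonotypes of 28 or more amino acids in red. The main peak lies at 14; the 158 red clonotypes have a median of 35.

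Several CDR3 amino acid sequences were listed with more than 1 nucleotide sequence. Of 4221 distinct amino acid sequences, 378 (8.96%, 95% interval 8.11 to 9.86) were carried by 2 or more nucleotide sequences. Counting only nucleotide sequences with 5 or more reads, it was 46 of 2605 (1.77%, 1.30 to 2.35). The shared sequences had a median length of 14 amino acids, as did the rest, and in the stricter count 13 against 14. The sequence with the most was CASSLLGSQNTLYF of TRBV12-1, with 6 nucleotide sequences, 4 of them with 5 or more reads. The best covered was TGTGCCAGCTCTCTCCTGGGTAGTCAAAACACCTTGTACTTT, with 17 reads; the other three had 10, 10 and 9 reads. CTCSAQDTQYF of TRBV1, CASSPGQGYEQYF, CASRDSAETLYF of TRBV13-1, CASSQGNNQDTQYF, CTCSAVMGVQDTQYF and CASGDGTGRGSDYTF had 4 nucleotide sequences each. In that order, 2, 3, 2, 1, 1 and 1 of the 4 had 5 or more reads. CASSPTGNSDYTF, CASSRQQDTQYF and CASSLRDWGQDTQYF had 3 each, of which 2 had 5 or more reads. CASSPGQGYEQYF was carried by 3 V segments, TRBV24, TRBV3 and TRBV5.

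The authors' normalization changed which clonotypes were largest. By normalized count, 17 of the 20 largest clonotypes were TRBV4 with TRBJ2-7; by raw count, 0 of 20 were, and only 2 clonotypes were in both lists. Those 2 were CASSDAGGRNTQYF, first in both, and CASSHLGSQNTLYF, second by reads and ninth by normalized count (114). The TRBV4 with TRBJ2-7 members were led by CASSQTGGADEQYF and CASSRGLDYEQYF, each with 31 reads and a normalized count of 145, then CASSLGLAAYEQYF (29 reads, 135 normalized) and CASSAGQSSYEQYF (28 reads, 131 normalized). The other members were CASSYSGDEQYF, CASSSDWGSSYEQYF, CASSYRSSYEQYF, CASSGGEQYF, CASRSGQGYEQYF, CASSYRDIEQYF, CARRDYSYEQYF, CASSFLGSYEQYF, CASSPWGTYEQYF, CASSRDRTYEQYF, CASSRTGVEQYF, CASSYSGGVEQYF and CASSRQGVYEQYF, with 21 to 26 reads and normalized counts of 98 to 121. The remaining one was a TRBV26 and TRBJ2-7 clonotype with 44 reads and a normalized count of 100, whose deposited CDR3 ended in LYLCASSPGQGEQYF.

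Per V segment, the ratio of normalized to raw count was highest for TRBV20 (3.60), TRBV4 (3.33) and TRBV5 (2.92). It was lowest for TRBV10 and TRBV22, whose normalized counts were all 0, and next for TRBV13-1 (0.557). Per J segment, the ratio was highest for TRBJ1-3 (2.40), TRBJ2-7 (1.59) and TRBJ1-4 (1.53), and lowest for TRBJ1-7 (0.429), TRBJ1-2 (0.559) and TRBJ2-3 (0.733). Over the 90 V-J pairs with 15 or more clonotypes the ratio ran from 0.301 to 34.2. The highest was that of TRBV5 with TRBJ2-5, whose 21 clonotypes had 26 reads in all, and 0 of them had 5 or more. In all, 179 clonotypes with 191 reads had a normalized count of 0.

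**Figure D3:**
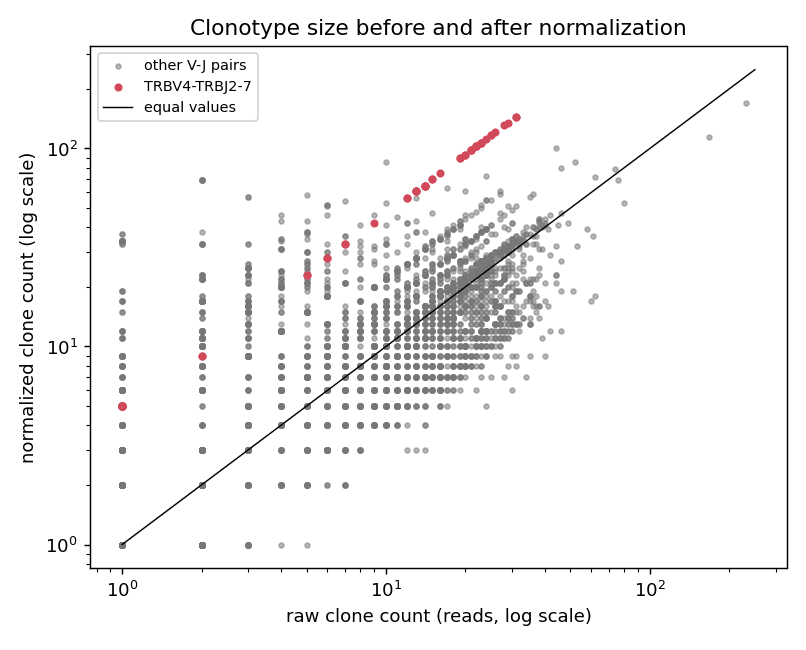
Normalized clone count (vertical axis, log scale) against raw clone count in reads (horizontal axis, log scale) for each clonotype with a normalized count above 0; the line marks equal values. Red points are TRBV4-TRBJ2-7 clonotypes, which reach a normalized count of 145 from 31 reads; the largest clonotype went from 232 reads to 169.

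The 100 largest clonotypes by normalized count reached down to a raw count of 2 reads. This ranking scales reads by a factor per V-J pair, so the factors enter the V and J make-up of the 100 by construction. The TRBV12-1 to TRBV17 block as a whole held 16.8% of the reads but 11.1% of the normalized counts. In this ranking the 100 largest used the block less often than the rest. Of them, 5 carried a segment of the block (5.0%, 95% interval 1.64 to 11.3), against 831 of the other 4546 (18.3%, 17.2 to 19.4). They used the TRBJ2 cluster in 94 cases (94.0%, 87.4 to 97.8), against 75.2% (73.9 to 76.4) of the rest, and 36 of the 100 were TRBV4 with TRBJ2-7. Their median CDR3 length was 14 amino acids, as in the rest, but the mean was 16.4 ± 7.63 against 14.6 ± 3.93 (SD over clonotypes). Lengths are as deposited, with the long TRBV26 CDR3s included. By raw count the means went the other way, 13.8 ± 3.03 for the 100 largest against 14.7 ± 4.07 for the rest. Ranked by raw count, a setting added after the data were seen, 18 of the 100 largest (18.0%, 11.03 to 26.9) carried a segment of the block, against 18.0% (16.9 to 19.1) of the rest, and the TRBJ2 cluster was used in 84.0% (75.3 to 90.6) against 75.4% (74.1 to 76.6).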

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

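D segments were outside the planned comparisons. TRBD2 lies downstream of the TRBJ1 cluster, so a direct joint of TRBD2 to TRBJ1 is not part of the usual order of rearrangement. Of 583 TRBJ1 clonotypes with a single D hit, 95 listed TRBD2 and 488 listed TRBD1, so TRBD2 made up 16.3% (95% interval 13.4 to 19.5). These counts stand out only because such hits were listed at all. A D hit is an alignment call, and no joint was checked in sequence. How often a D segment is miscalled was not measured, with either J cluster. Among 2120 TRBJ2 clonotypes with a single D hit, 1248 listed TRBD2 (58.9%, 56.7 to 61.0). No D hit was given for 382 TRBJ1 and 923 TRBJ2 clonotypes. In the list of read numbers, another column no comparison used, 245 clonotypes had more reads than their clone count, 391 reads in all.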

How the results depend on the processing

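No paired analysis was possible because only 1 library was analysed, and no replicate could be left out. Of 40 results under another setting, 25 stayed inside the counting interval of the reported value and 15 moved. Of the 25, 6 could not move because each listed clonotype was productive (the productive share, and taking all clonotypes), and 5 were the median CDR3 length, a whole number that small shifts do not change, which leaves 14. The 4 that leave out the TRBV4-TRBJ2-7 pair, restart CDR3s or rank by raw count were chosen after seeing the data. Clonality (0.0541) was 0.0362 with a clone count of at least 2, 0.0461 with near-copies joined, 0.0563 from raw counts, 0.0517 for amino acid clonotypes, 0.0501 with the reads thinned to 50 percent and 0.0484 without TRBV4-TRBJ2-7. The share of the 10 largest (2.40%) was 2.05% from raw counts, 2.73% thinned and 1.82% without TRBV4-TRBJ2-7. The V block (18.0%) held 11.1% by normalized and 16.8% by raw counts, and the TRBJ2 cluster (75.6%) held 79.4% by normalized counts. Amino acid sequences with several nucleotide sequences (8.96%) were 3.20% with a clone count of at least 2 and 6.46% with near-copies joined. The block's share of the 100 largest (5.0%) was 18.0% when ranked by raw counts. The median CDR3 length was 14 in each setting run. The cause of these moves was not tested beyond what each setting removes by construction. Depth limits the rare end: at 1 or 2 reads a template and a copying error look alike.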

Other observations

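The values and tests here were chosen after the data were seen, except the test of TRBV26 length, which was set after the long CDR3s and an example of their sequence had been seen but before the restarted lengths were computed. Among the 20 largest clonotypes by reads, 8 used a V segment of the TRBV12-1 to TRBV17 block (40.0%, 95% interval 19.1 to 63.9), against 17.9% of the rest (16.8 to 19.0). By normalized count it was 2 of 20. The excess did not extend to larger sets by reads: it was 18 of the 100 largest (18.0% against 18.0% of the rest) and 67 of the 500 largest (13.4%, 10.5 to 16.7, against 18.5%, 17.4 to 19.8). The 4 largest listed clonotypes by reads all came from the block: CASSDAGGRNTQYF of TRBV13-3, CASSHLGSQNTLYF of TRBV12-1, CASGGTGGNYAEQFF of TRBV13-2 and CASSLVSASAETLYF of TRBV16 (76 reads). The TRBV12-1 and TRBJ2-4 clonotype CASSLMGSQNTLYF, with 58 reads among the 20 largest, has the length of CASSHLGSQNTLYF and of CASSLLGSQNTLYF and ends in the same GSQNTLYF. Each of these occurs with TRBV12-1 and TRBJ2-4, so ends taken from those segments are shared by construction. How much of the likeness lies beyond the segments was not measured. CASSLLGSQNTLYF itself also appeared with a TRBJ2-3 ending in 2 nucleotide sequences of 2 reads each, beside TRBJ2-4 forms of 9 and 17 reads. By a stricter rule, which these 2 do not meet, clonotypes equal to one at least 10 times larger except in the last 9 bases, and with another J, numbered 84 in the library (1.81%, 1.44 to 2.23), with 92 reads and at most 2 reads each.

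The first pattern is the presence of the V block in a library of the FVB strain. Ties between V segments inside and outside the block are argued against, since 99.9% of the 836 block clonotypes listed only V segments of the block. Of all clonotypes, 98.5% listed a single V hit. Hit lists cannot show a segment wrongly called outright, and the germline reference is not named, so wrong calls of that kind stay open. Carryover of a few reads from other libraries is argued against for the block as a whole, since its median clonotype had 6 reads against 7 outside it, a ratio of 0.857 (bootstrap interval 0.75 to 1.0). An animal that carries the block and templates from animals that carry it cannot be told apart in 1 library, where the block made up 18.0% of clonotypes. The deletion rests on background knowledge of the strain and was not checked in these animals; other libraries of the series and the germline locus would bear on it.

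The second pattern is that clonotype size by normalized count depends on the V-J pair. The authors' factor for TRBV4-TRBJ2-7 (TRBV4_TRBJ2-7) was 4.67, and 0 of the 20 largest by raw count were of that pair against 17 by normalized count, which restates the pattern and does not test what sets the ranking. Whether this pair amplified poorly while its clonotypes were of ordinary size stays open: its 43 clonotypes with 5 or more reads had a median of 19 reads, 1.36 times the median pair, with a bootstrap interval from 1.0 to 1.5 that reaches equality, and a lower bound tried after this result would have argued against it but is hard to reach once smaller clonotypes are left out. Whether the factors even out amplification in general also stays open: with clonotypes of 5 or more reads, the minimum chosen first, the SD of the log2 median size over 52 pairs was 0.30 higher after normalization (0.10 to 0.52), but that minimum itself narrows the raw spread (0.44, against 0.97 with 2 or more reads) and so decides nothing, and with 2 or more reads, added after that result, the change was -0.25 over 65 pairs (-0.49 to 0.01). Over those pairs, the Spearman correlation of the factor with the median raw size was -0.58 with 2 or more reads and -0.26 with 5 or more. With no minimum, the 60 TRBV4-TRBJ2-7 clonotypes had a median of 13.5 reads, against 7 over all listed clonotypes. A larger true size of TRBV4-TRBJ2-7 clones remains possible and was not tested.

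The third pattern is the group of long TRBV26 CDR3s. A candidate explanation is a CDR3 start set upstream of the conserved cysteine for this segment. Of the 158 long CDR3s, 156 held LYLCA. Restarted at the first cysteine followed by an alanine, where there was one, the 158 had a median length of 14 amino acids. This was equal to that of the other clonotypes. The longest was then 35. The values are in line with that explanation; no biological explanation was tested.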
